A study of Homo sapiens with 6 samples.

How the data were processed

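RNA-seq of SK-N-BE(2) cells was used from 6 libraries, 3 treated with DMSO and 3 with 1 µM NEN for 24 h, grouped by the treatment given in the labels. Per the labels' protocols, total RNA was extracted with Trizol, and the library text names both polyA capture and rRNA removal without saying which was used. Reads were quantified with kallisto and the hg19 build is named, per the submitters' processing notes; versions are not given in the sources used here. The deposited values are TPM, 1 column per library, with 35130 gene names in the same order. The listed genes of a library sum to between 929054 and 933500 TPM, and TPM over all transcripts would sum to more, so part of each library lies outside the listed names. Of 16042 names of long noncoding genes in GENCODE release 29, 158 are listed. There are 27 names that look like dates, as spreadsheet programs write some gene symbols, and 2 repeated names. TPM holds no read counts, so depth is unknown and no counting intervals are given.

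The design foresaw count tables or TPM, and the test for TPM was used. Genes with a mean of at least 1 TPM over the 6 libraries were kept, 12576 in all. Values were taken as log2(TPM + 1) with a pseudocount of 1, and limma (version 3.58.1, in R 4.3.3) was fitted with group alone and with its trend and robust settings. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Gene lists were tested with camera in limma at its preset inter-gene correlation of 0.01, adjusted over the 35 of 40 lists with at least 5 tested members. Lists, tests and alternatives were fixed before the data were examined. Of 867 list symbols, 847 were found under the symbol, 14 under an older symbol and 6 were not matched. A further 15 lists were written after the main results were seen and are adjusted among themselves. Several genes belong to more than 1 list, such as RET, and VIM is in a fixed and an added list.

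Genes named in the text follow a rule. It takes the 10 largest rises and 10 largest falls among genes past the threshold whose 3 NEN libraries all lie on one side of the 3 DMSO libraries and whose higher mean is at least 10 TPM, leaving out clone-named, noncoding and pseudogene-like entries. It always takes MYCN, MYC, CTNNB1, HIF1A, EPAS1 and TXNIP, and up to 4 members per list with the smallest adjusted p. CDKN1A, ATF4, EGLN3, EGLN1 and ANKRD37, and the genes listed near the floor, were named after their values were seen. The results of 1 fixed list, which stays in the counts of lists and their adjustment, and of 1 member of another are not reported here.

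The gene test was checked on data simulated for NEN against DMSO with 12576 genes, of which 200 were changed, in 5 draws. It recovered 50.9% of changes of 1.5-fold and 90.3% of changes of 2-fold, with 7.34% and 5.92% of calls false. The simulated genes were independent, which real genes are not. Changes were planted only in genes with a DMSO level above 2 on the log2(TPM + 1) scale. In the simulation 200 of 12576 genes were changed, while 30.0% of tested genes were called in the data. These rates may therefore not hold for this comparison, nor for low genes. In 20 draws the list test made 1 call in total among 35 unchanged lists and recovered a planted fall of 0.5 on the log2 scale in 20 draws. Genes were independent in these draws too, so they do not show how the list test behaves where list members are correlated.

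The alternatives were a replicate block, leaving out each library, no filter and a minimum of 5 TPM, median-ratio scaling and quantile normalization. Others were limma without trend and robust settings, pseudocounts of 0.1 and 5, and a minimum log2 fold change of 1. For lists they were an estimated correlation in camera, and fry. With an estimated correlation, camera also takes its p from the 4 residual degrees of freedom instead of the number of genes. Its p can therefore rise without a higher correlation. Added after the data were seen were a correction of each library for its trend with transcript length and GC content (loess, span 0.3, degree 1, on 11741 genes, 93.4% of those tested, with a value for all 56 ribosomal protein genes), and the HIF list without DDIT4 and the ribosomal protein genes with a mean of at least 100 TPM, each at the preset and at an estimated correlation. Length and GC content came from GENCODE release 29, whose genome build differs from that of the files, so no coordinates are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.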

Results

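RNA-seq was carried out on SK-N-BE(2) cells, a human neuroblastoma line with amplification of MYCN, grown in dishes and treated for 24 h with 1 µM NEN or with the solvent DMSO. NEN is named in the labels by its abbreviation alone. Published work on neuroblastoma uses NEN for niclosamide ethanolamine, an uncoupler of mitochondrial respiration, and that identity is taken here as background. Each group held 3 libraries that the labels call biological replicates. Values were transcript abundances scaled by transcript length and library total (TPM) for 35130 gene names per library. TPM keeps no record of sequencing depth, so depth is unknown. Between 17285 and 18041 genes lay above 0 in each library, and 12576 genes with a mean of at least 1 TPM were tested. The single comparison of the design asks which transcripts differ between NEN-treated and DMSO-treated cells. Fold changes are NEN minus DMSO on the log2(TPM + 1) scale, which understates the change of low genes, and are given ± SE with adjusted p-values from limma. Group levels are mean ± SD with n = 3.

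NEN-treated cells had lower mRNA levels of S phase genes (35 of 38 tested) and higher levels of ATF4 targets (16 of 25), with camera adjusted p = 3.48e-21 and 7.24e-08 (adjusted p = 0.0972 and 0.107 with an estimated correlation). GDF15, a secreted stress cytokine, rose by 3.32 ± 0.17 on the log2 scale, from 0.68 ± 0.30 to 15.5 ± 0.78 TPM. DDIT3, which encodes the stress transcription factor CHOP, rose from 21.6 ± 3.8 to 71.6 ± 1.5 TPM, and DDIT4, an inhibitor of mTORC1, rose from 31.1 ± 6.7 to 144.1 ± 4.4 TPM. UHRF1, which brings DNMT1 to replicated DNA, had a fold change of -2.18 ± 0.28 and went from 43.2 ± 7.1 to 9.2 ± 4.3 TPM. CDC6, a replication licensing factor, went from 26.7 ± 2.0 to 5.6 ± 1.1 TPM. In all, 3773 genes, 30.0% of those tested, passed an adjusted p of 0.05, of which 1699 rose and 2074 fell. A fold change of at least 1 on the log2 scale was found for 198 of the genes that rose and 158 of those that fell. The 2 groups did not overlap for 5884 genes, 46.8% of those tested, where chance gives 10%.

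Among the 10 largest rises, the others were NTNG2, a netrin-family membrane protein (2.55 ± 0.25), BBC3, the pro-apoptotic BH3 protein PUMA (2.34 ± 0.13), SNAI1, a transcription factor of epithelial-mesenchymal transition (2.13 ± 0.15), AMOT (1.90 ± 0.14), RASA4 (1.85 ± 0.13), KLHDC8A (1.65 ± 0.18) and AKNA (1.65 ± 0.40, adjusted p = 0.0193). The call of AKNA was lost without DMSO replicate 3 (1.66), NEN replicate 1 (1.49) or NEN replicate 3 (1.59), and with no filter (1.65). The other large falls were in CCNE2 (-1.84 ± 0.26) and CCNE1 (-1.52 ± 0.19), which encode E-type cyclins, MCM10 (-1.67 ± 0.14), FEN1 (-1.60 ± 0.09), DGCR8, a subunit of the microRNA-processing complex (-1.64 ± 0.14), the chemokine CXCL12 (-1.59 ± 0.17), CYB561, a cytochrome of catecholamine vesicles (-1.53 ± 0.09), and TCF7, a Wnt-pathway transcription factor (-1.50 ± 0.21). Adjusted p-values of these 20 genes lay between 0.000215 and 0.0193.

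**Figure D1:**
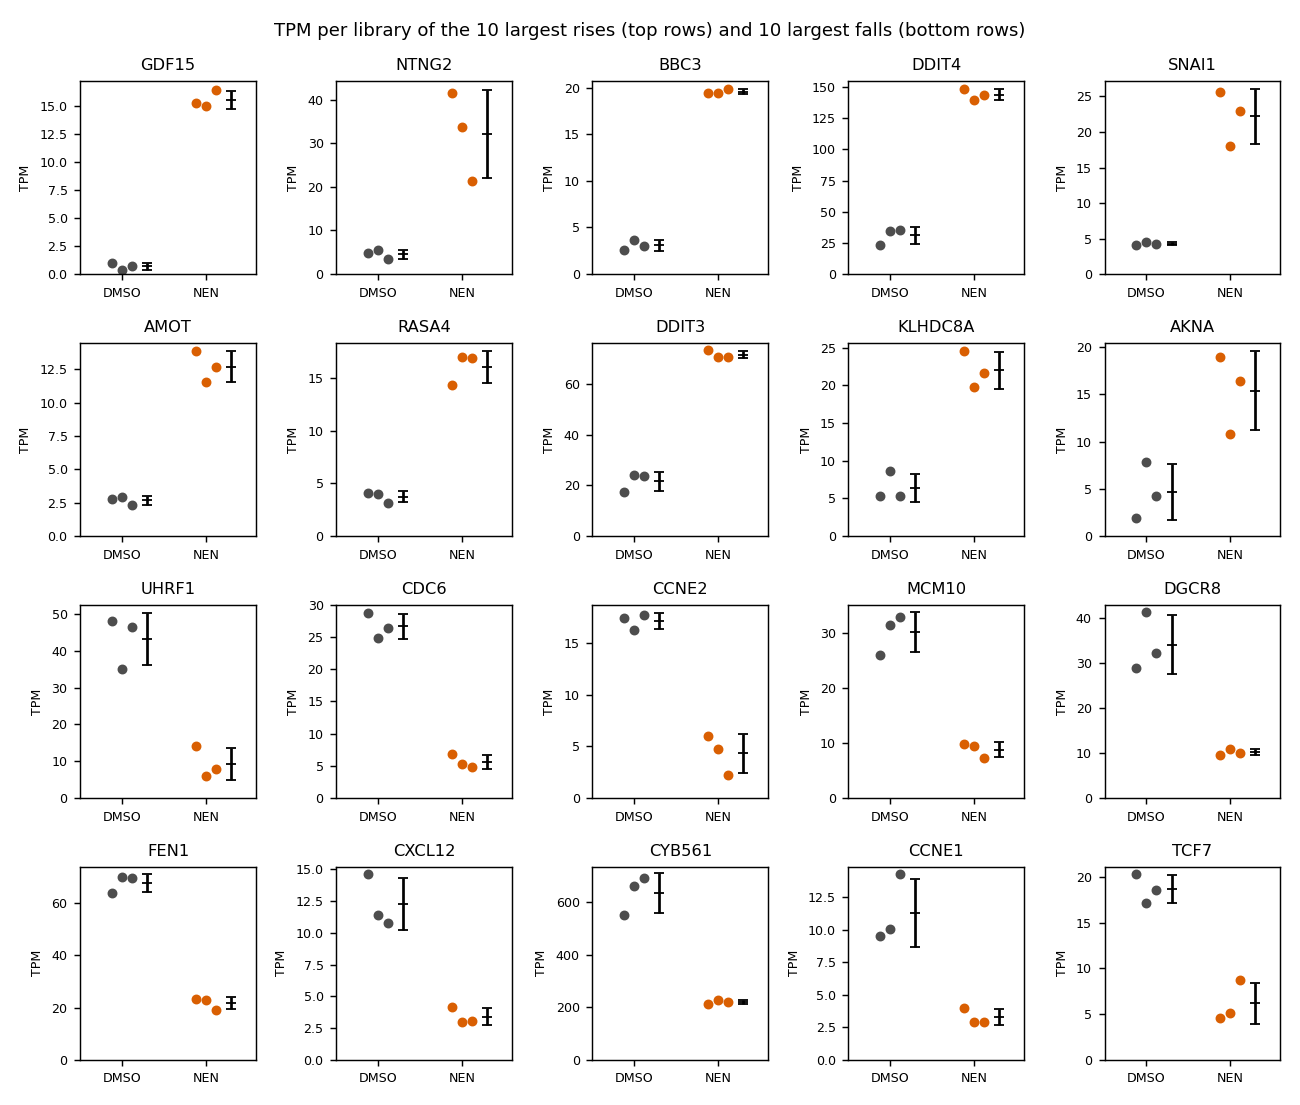
TPM (vertical axis, from 0) in each of the 3 DMSO and 3 NEN libraries for the 10 genes with the largest rise and the 10 with the largest fall, with points for libraries and a dash with bars for the mean and SD. For each gene the NEN libraries lie on one side of the DMSO libraries, as for GDF15 with means of 0.68 and 15.5 TPM.

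MYCN, the amplified oncogene of this line, was high in both groups and rose from 1163 ± 104 to 1455 ± 66 TPM (0.33 ± 0.07, adjusted p = 0.0169). That call was lost without NEN replicate 1 (0.29) and with limma's plain settings (0.33). MYC was below the filter, with 0 TPM in DMSO replicate 1 and 0.53 and 0.51 TPM in the other DMSO libraries, against 0.036, 0 and 0.28 TPM in the NEN libraries. HIF1A mRNA fell from 138.8 ± 9.1 to 102.6 ± 5.8 TPM (-0.43 ± 0.07, adjusted p = 0.00483). EPAS1, which encodes HIF-2 alpha, had 28.3 ± 1.4 and 28.3 ± 2.0 TPM (adjusted p = 0.998). CTNNB1, which encodes beta-catenin, had -0.39 ± 0.17 (adjusted p = 0.132), and passed the threshold without NEN replicate 2 (-0.58). TXNIP, a glucose-regulated arrestin, had -0.22 ± 0.06 (adjusted p = 0.0333), a call lost on leaving out any 1 of the 6 libraries (-0.25 to -0.20). The TXNIP call was also lost in limma with the replicate block (adjusted p = 0.0707), no filter (0.0552), quantile normalization (0.0707), plain settings (0.0662) and length and GC correction (0.0929).

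Genes of S phase and DNA replication fell together: 35 of 38 tested members fell and 0 rose, with a median fold change of -0.95. PCNA, the replication sliding clamp, fell from 450.9 ± 19.3 to 175.5 ± 8.9 TPM, MCM5 from 142.4 ± 9.1 to 51.0 ± 4.4 TPM and TK1 from 127.2 ± 4.4 to 56.0 ± 2.0 TPM. Adjusted over the list alone, 37 fell. Camera, a test that compares a list with all other genes, gave an adjusted p = 3.48e-21 (adjusted p = 0.0972 with an estimated correlation). In the G2/M and mitosis list 15 of 35 members fell and 1 rose (18 fell and 1 rose adjusted over the list alone), with a median of -0.23, or -0.149 after quantile normalization. CDK1, the mitotic kinase, fell by 0.48 ± 0.06, BIRC5 by 0.48 ± 0.06 and MKI67 by 0.58 ± 0.08. The list's camera test had an adjusted p = 0.000266 (adjusted p = 0.376 with an estimated correlation).

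**Figure D2:**
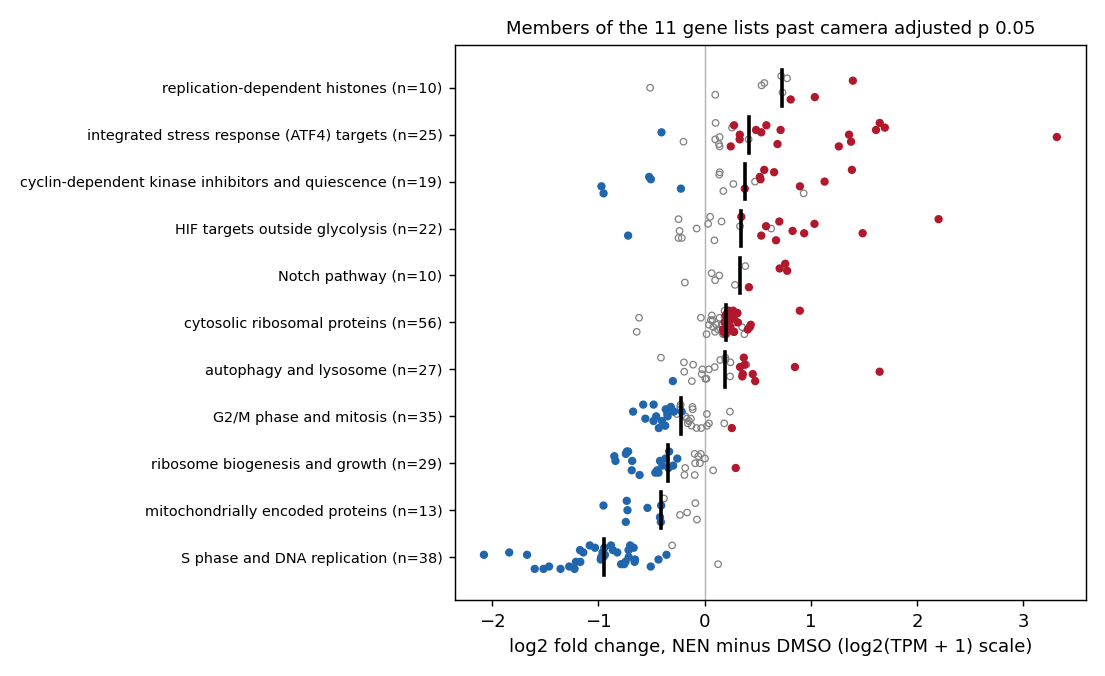
Log2 fold change, NEN minus DMSO, of each tested member (points) of the 11 gene lists past camera's adjusted p of 0.05, with red and blue points for members that rose or fell at adjusted p of 0.05, open points for the rest and black lines for list medians. Medians run from -0.95 for S phase genes to 0.73 for histone genes.

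Of the list of cyclin-dependent kinase inhibitors and quiescence genes, 8 of 19 rose and 5 fell (12 and 5 adjusted over the list alone). CCNG2 rose by 1.39 ± 0.10 and YPEL5 by 1.13 ± 0.10, while RBL1, a pocket protein related to RB1, fell by 0.97 ± 0.12. CDKN1A, which encodes the inhibitor p21, fell from 65.0 ± 1.6 to 45.6 ± 3.9 TPM. By camera, the list had an adjusted p = 0.0434 (adjusted p = 0.441 with an estimated correlation), and the call was lost without DMSO replicate 1 (adjusted p = 0.0561) or NEN replicate 3 (adjusted p = 0.0583), with the replicate block (0.0551), 5 TPM (0.0688), plain limma settings (0.0599) and length and GC correction (0.0743). Apoptosis regulators went both ways, with 5 of 18 up and 4 down (5 and 5 adjusted over the list alone; adjusted p = 0.802). BMF, a BH3 protein, rose by 1.65 ± 0.19, and MCL1, an anti-apoptotic protein, fell by 0.46 ± 0.05. The median of that list was -0.02, its mean 0.21.

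Targets of the integrated stress response factor ATF4 rose in 16 of 25 cases and fell in 1 (17 and 1 adjusted over the list alone), with a median of 0.41. TRIB3, a pseudokinase, rose from 10.3 ± 0.8 to 33.7 ± 1.0 TPM, and PPP1R15A, a phosphatase subunit that acts on eIF2 alpha, from 7.2 ± 0.9 to 24.6 ± 3.3 TPM. Camera gave an adjusted p = 7.24e-08 (adjusted p = 0.107 with an estimated correlation). In the endoplasmic reticulum unfolded protein list 2 of 20 members rose and 6 fell, also when adjusted over the list alone (adjusted p = 0.188). HERPUD1 rose by 0.67 ± 0.08, SDF2L1 fell by 0.60 ± 0.06 and DNAJB11 by 0.58 ± 0.08. Of the cytosolic heat shock list 1 of 10 rose and 5 fell, likewise adjusted over the list alone (adjusted p = 0.0781). DNAJA1, an HSP40 co-chaperone, fell from 195.3 ± 9.1 to 92.4 ± 2.7 TPM, and HSPB1 rose by 0.46 ± 0.06. Mitochondrial chaperones and proteases had 2 of 14 up and 3 down (3 and 3 adjusted over the list alone; adjusted p = 0.802), with a fall of TIMM17A by 0.52 ± 0.07 and a rise of TRAP1 by 0.44 ± 0.10, which lost its call without NEN replicate 1 (0.383) or NEN replicate 3 (0.423). NRF2 targets had 4 of 19 up and 2 down, as adjusted over the list alone (adjusted p = 0.970). TXNRD1 fell by 0.60 ± 0.06 and FTL, the ferritin light chain, rose by 0.40 ± 0.05.

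Targets of HIF outside glycolysis rose in 10 of 22 cases and fell in 1, as adjusted over the list alone, with a median of 0.34. Besides DDIT4, ZNF395 rose by 0.83 ± 0.10, NDRG1 from 5.0 ± 1.2 to 15.8 ± 2.9 TPM and KDM3A, a histone demethylase, by 0.67 ± 0.09. The list's camera test had an adjusted p = 0.00398 (adjusted p = 0.229 with an estimated correlation). Of the glycolysis and glucose transport genes 8 of 21 rose and 2 fell (11 and 4 adjusted over the list alone). ALDOC, an aldolase, rose from 21.9 ± 4.1 to 53.3 ± 2.0 TPM, the glucose transporter SLC2A3 from 3.5 ± 0.6 to 9.4 ± 0.2 TPM, and PGAM1 fell by 0.44 ± 0.06. By camera, the list had an adjusted p = 0.0702, and 0.0470 without DMSO replicate 3.

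mRNAs encoded by mitochondrial DNA fell in 8 of 13 cases and rose in 0 (9 fell adjusted over the list alone), with a median of -0.41. MT-CO3 fell from 13480 ± 283 to 9293 ± 557 TPM, MT-ND1 from 4643 ± 568 to 2783 ± 162 TPM and MT-ND2 by 0.73 ± 0.11. Their share of the summed TPM was 11.6%, 9.57% and 9.53% in the DMSO libraries and 7.49%, 8.32% and 8.56% in the NEN libraries. Against the DMSO mean, the mean of the list was -0.574, -0.407 and -0.374 in NEN replicates 1 to 3. That of the histone genes, listed as a possible sign of RNA selection, was 0.733, 0.653 and 0.461. Camera gave an adjusted p = 0.000784 (adjusted p = 0.465 with an estimated correlation). Nuclear genes for respiratory chain and ATP synthase subunits had 4 of 60 up and 4 down (2 and 3 adjusted over the list alone; adjusted p = 0.305). CYCS, which encodes cytochrome c, fell by 0.61 ± 0.10 and ATP5J by 0.29 ± 0.06, while NDUFS7, a complex I subunit, rose by 0.30 ± 0.06, a call lost after length and GC correction (0.039). Of the citric acid cycle genes 6 of 19 rose and 1 fell (6 and 2 adjusted over the list alone; adjusted p = 0.268), the fall being that of IDH3A, by 0.51 ± 0.09. PC, pyruvate carboxylase, rose by 0.34 ± 0.06, a call lost after length and GC correction (0.184), and SUCLG2 by 0.45 ± 0.10, a call lost without NEN replicate 3 (0.378). Of the mitochondrial biogenesis factors 2 of 16 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.169). ESRRA, an orphan nuclear receptor, rose by 0.83 ± 0.10, and TFAM, which packages mitochondrial DNA, fell by 0.68 ± 0.09.

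Ribosome biogenesis and growth genes regulated by MYC or MYCN fell in 18 of 29 cases and rose in 1, as adjusted over the list alone, with a median of -0.34. MRTO4, a ribosome assembly factor, fell from 75.4 ± 1.2 to 41.4 ± 0.9 TPM, NOP56, a nucleolar protein, by 0.84 ± 0.07 and NIP7 by 0.61 ± 0.07. The list's camera test had an adjusted p = 2.39e-06 (adjusted p = 0.0972 with an estimated correlation). Cytosolic ribosomal protein genes rose in 25 of 56 cases and fell in 0 (34 rose and 2 fell adjusted over the list alone), with a median of 0.20, or 0.118 after quantile normalization. RPL3 rose from 1995 ± 38 to 2644 ± 22 TPM, RPL12 by 0.42 ± 0.05 and RPL7A by 0.30 ± 0.05. The share of summed TPM taken by this list was 13.5% to 14.3% in DMSO and 15.9% to 16.5% in NEN libraries. By camera, the list had an adjusted p = 6.43e-09 (adjusted p = 0.160 with an estimated correlation). Replication-dependent histone genes, listed as a possible sign of RNA selection, lay 0.461 to 0.733 above the DMSO mean in the same NEN libraries on the log2 scale. RPS27 and a few other members were listed at levels far under the rest of the list, so their own fold changes are uncertain.

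In the DNA methylation and 2-hydroxyglutarate list 5 of 16 members rose and 4 fell, also adjusted over the list alone (adjusted p = 0.911). Besides UHRF1, DNMT1, the maintenance methyltransferase, fell from 140.0 ± 4.7 to 90.5 ± 4.9 TPM, and TDG, a glycosylase of active demethylation, from 70.3 ± 3.0 to 35.2 ± 1.9 TPM. IDH1, an isocitrate dehydrogenase, rose by 0.30 ± 0.06.

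Neuronal and lineage genes moved in both directions. Of the neuronal differentiation genes 12 of 29 rose and 4 fell (12 and 7 adjusted over the list alone; adjusted p = 0.212). VGF, a secreted neuronal protein, rose from 289.6 ± 15.2 to 699.9 ± 31.4 TPM, NRCAM, a cell adhesion molecule, by 0.55 ± 0.08, and RET, a receptor tyrosine kinase, fell from 340.6 ± 2.7 to 210.5 ± 5.7 TPM. Adrenergic core transcription factors had 8 of 18 up and 5 down (10 and 5 adjusted over the list alone; adjusted p = 0.205). PHOX2A rose from 428.3 ± 15.5 to 749.1 ± 34.4 TPM and TBX2 by 0.85 ± 0.07, while HAND1 fell from 619.6 ± 35.8 to 322.2 ± 5.8 TPM. For catecholamine synthesis and handling 2 of 10 rose and 4 fell, likewise adjusted over the list alone (adjusted p = 0.327). DDC, which makes dopamine, fell by 0.45 ± 0.05, and DBH, which makes noradrenaline, rose by 0.41 ± 0.06. Of the mesenchymal neuroblastoma genes 4 of 15 rose and 1 fell, also adjusted over the list alone. TWIST1 rose from 99.1 ± 2.8 to 200.4 ± 12.3 TPM, SNAI1 from 4.3 ± 0.2 to 22.2 ± 3.9 TPM and VIM by 0.51 ± 0.05. Camera gave an adjusted p = 0.0587 for this list, and it was 0.0489 without DMSO replicate 3, 0.0311 without NEN replicate 1, 0.0456 without NEN replicate 2 and 0.156 without NEN replicate 3. The mean of the list lay 0.484 above the DMSO mean in NEN replicate 3 and 0.298 and 0.291 above it in NEN replicates 1 and 2. For stromal markers these differences were 0.386, 0.023 and -0.147 and for epithelial markers 0.455, -0.239 and -0.1, in the same order.

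Notch pathway genes rose in 4 of 10 cases and fell in 0, as adjusted over the list alone. HES1, a target of Notch, rose from 9.5 ± 0.8 to 16.7 ± 0.8 TPM and DTX1 by 0.78 ± 0.17. The list's camera test had an adjusted p = 0.0434 (adjusted p = 0.351 with an estimated correlation), and 0.0778 without DMSO replicate 1. The Notch call was also lost with the replicate block (adjusted p = 0.0552), no filter (0.0993), a minimum of 5 TPM (0.127), quantile normalization (0.0516) and length and GC correction (0.173). Its median of 0.335 became 0.138 without a filter, 0.184 with a pseudocount of 5 and 0.143 after length and GC correction. Wnt/beta-catenin targets had 2 of 10 up and 6 down, as adjusted over the list alone (adjusted p = 0.212). CCND1, which encodes cyclin D1, fell from 414.0 ± 40.5 to 259.6 ± 3.4 TPM and BAMBI by 0.45 ± 0.09. Immediate early genes had 2 of 16 up and 4 down, also adjusted over the list alone (adjusted p = 0.518), with a fall of EGR1 by 1.15 ± 0.09 and a rise of NR4A1 by 0.93 ± 0.11. Of the retinoic acid response list 2 of 12 rose and 3 fell, likewise adjusted over the list alone (adjusted p = 0.970), with a fall of MEIS2 by 0.62 ± 0.09 and a rise of RARG by 0.89 ± 0.19. In the interferon list 0 of 15 rose and 2 fell, as adjusted over the list alone (adjusted p = 0.802). These were OAS1, an antiviral synthetase, which fell from 126.5 ± 14.5 to 52.5 ± 3.0 TPM, and OAS3, by 0.64 ± 0.06. The median of the interferon list was 0.03 and its mean -0.09.

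Autophagy and lysosome genes rose in 9 of 27 cases and fell in 1, as adjusted over the list alone. GABARAPL1, an autophagosome protein, rose from 8.1 ± 5.0 to 25.3 ± 4.1 TPM, WIPI1 by 0.85 ± 0.16 and TFE3, a transcription factor of lysosomal genes, by 0.48 ± 0.09. By camera, the list had an adjusted p = 0.0330 (adjusted p = 0.376 with an estimated correlation), a call lost without DMSO replicate 2 (adjusted p = 0.0538) or NEN replicate 3 (adjusted p = 0.0583). Cholesterol genes had 7 of 22 up and 3 down (8 and 3 adjusted over the list alone; adjusted p = 0.0696). MSMO1 rose by 0.83 ± 0.07, INSIG1 by 0.89 ± 0.07 and SREBF2, which encodes the SREBP-2 transcription factor, by 0.51 ± 0.06, while SC5D fell by 0.46 ± 0.07. Fatty acid synthesis genes had 3 of 12 up and 0 down (2 and 0 adjusted over the list alone; adjusted p = 0.133), and FASN rose from 160.2 ± 5.0 to 257.7 ± 15.4 TPM. Fatty acid oxidation genes had 3 of 18 up and 1 down (0 and 0 adjusted over the list alone; adjusted p = 0.668). ACADS, with 0.68 ± 0.16, lost its call without DMSO replicate 2 (0.64) or NEN replicate 2 (0.56).

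Markers of other cell types were few. Of the stromal markers 2 of 9 rose and 1 fell, as adjusted over the list alone (adjusted p = 0.802; median -0.09, mean 0.09), the most abundant being THY1 with 366.3 ± 22.4 and 287.9 ± 9.3 TPM. CD68, the 1 tested blood and immune marker, rose from 8.4 ± 1.3 to 16.2 ± 1.2 TPM. EGFL7, the most abundant of 2 tested endothelial markers, rose from 44.3 ± 4.3 to 61.7 ± 4.5 TPM, a call lost after correction for transcript length and GC content (0.19). The 5 epithelial markers (adjusted p = 0.802) and 2 Schwann cell markers had 0 calls, with KRT19 at 3.3 ± 1.3 and 2.3 ± 0.9 TPM and ERBB3 at 10.5 ± 2.3 and 10.7 ± 3.4 TPM. TDRD1 was the 1 germline gene tested, with 29.5 ± 1.5 and 28.8 ± 0.7 TPM. Of the replication-dependent histone genes, listed as a possible sign of RNA selection, 3 of 10 rose and 0 fell (5 and 1 adjusted over the list alone). HIST3H2A had 12.9 ± 1.0 and 35.6 ± 3.4 TPM. Camera gave this list an adjusted p = 0.0155 (adjusted p = 0.376 with an estimated correlation), a call lost with 5 TPM (0.127) or no filter (0.221). Its median of 0.73 became 0.152 over all 19 genes without a filter, and 0.313 with a pseudocount of 5. TUG1, the 1 nuclear noncoding RNA tested, had 10.4 ± 1.2 and 8.5 ± 1.2 TPM.

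On the first principal component (47.5% of variance) the DMSO libraries lay between -29.16 and -22.68 and the NEN libraries between 24.55 and 28.08. DMSO replicate 1 stood apart on the second component (16.3%) at 29.42, with the other 5 libraries between -16.84 and 2.96. Of 35 lists with at least 5 tested members, 11 passed camera's adjusted p of 0.05 with its preset correlation, 7 higher and 4 lower. With a correlation estimated from these 6 libraries, 0 passed. That setting also takes its p from the 4 residual degrees of freedom. For the ribosome biogenesis and growth list the estimate was -0.0078, under the preset 0.01, yet camera's p rose from 2.73e-07 to 0.00434. For Notch it was -0.032, and p rose from 0.0129 to 0.0602. For these lists the loss is therefore not a sign of high correlation. All other called lists had estimates above the preset, from 0.015 for HIF targets to 0.63 for mitochondrially encoded mRNAs. It was 0.13 for G2/M and for quiescence, 0.12 for histones and 0.094 for S phase. For those lists correlation and degrees of freedom both raise p, and their parts were not separated.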

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

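The correction for length and GC content and the changed memberships of lists were chosen after the data were seen; the other settings were planned. The count of 3773 genes lay between 2582 and 3468 on leaving out 1 library, with 1063 to 1554 that rose (1063 without NEN replicate 1, against 1699) and 1402 to 1914 that fell, and it was 356 with a log2 fold change of at least 1, a stricter criterion by construction. Under every other setting it stayed within 1.5 times. Genes that rose made up 45.0% of the calls, 49.7% after median-ratio scaling and 50.1% after quantile normalization. No pairing by replicate number was seen: deviations from the group means correlated at 0.012, -0.008 and -0.028 for the same numbers. Not every library correlated best with its own number. With so few libraries this cannot exclude a shared day, which the labels do not state. With the number as a block 2977 genes and 9 lists were called, the quiescence list (adjusted p = 0.0551) and the Notch list (adjusted p = 0.0552) no longer among them. Of 175 called genes tracked, the named ones among them, 154 kept direction and call under each setting run. EPAS1, near 0, changed sign on leaving out single libraries (-0.044 to 0.053) and after length and GC correction (-0.016).

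The 11 called lists became 9 to 13 on leaving out 1 library (5 to 9 higher, 4 lower), and 7 of the 11 kept their call under each setting other than an estimated correlation and fry. With a minimum of 5 TPM, 4 lists were higher. With an estimated correlation 0 lists passed, with adjusted p = 0.0972 for S phase and for ribosome biogenesis, 0.107 for ATF4 targets, 0.160 for ribosomal proteins, 0.229 for HIF targets (0.376 without DDIT4), 0.351 for Notch, 0.376 for G2/M, autophagy and histones, 0.441 for quiescence and 0.465 for mitochondrially encoded mRNAs. Fry, which does not compare a list with other genes, called 26 lists by direction and 34 in either direction. Its added calls had adjusted p = 0.00287 for glycolysis, 0.0479 for the citric acid cycle and for fatty acid synthesis, 0.0140 for DNA methylation, 0.00346 for mitochondrial biogenesis, 0.0131 for the unfolded protein list, 0.00198 for heat shock, catecholamine and mesenchymal genes, 0.0396 for neuronal genes, 0.00920 for cholesterol, 0.00195 for Wnt, 0.00635 for immediate early genes and, in the opposite direction to camera, 0.0176 for retinoic acid.

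The quiescence list lost its call with a minimum of 5 TPM (adjusted p = 0.0688), plain limma settings (0.0599) and length and GC correction (0.0743), and ranged from 0.0342 to 0.0583 on leaving out 1 library. The Notch list lost it without a filter (0.0993), with 5 TPM (0.127), quantile normalization (0.0516) and length and GC correction (0.173), with a range of 0.0342 to 0.0778. Histones lost it without a filter (0.221) and with 5 TPM (0.127), and autophagy ranged from 0.0154 to 0.0583. Glycolysis passed without a filter (0.0362; range 0.0470 to 0.149), heat shock after length and GC correction (0.0475), the mesenchymal list on leaving out single libraries (0.0311 to 0.156) and fatty acid synthesis after quantile normalization (0.0441). Cholesterol passed without a filter (0.0385), after median-ratio scaling (0.0424), quantile normalization (0.0160) and length and GC correction (0.0480). Lists far from the threshold changed direction. They were NRF2 targets after median-ratio scaling (0.980), quantile normalization (0.956) and length and GC correction (0.994; range 0.838 to 0.999), interferon without a filter (0.945; range 0.606 to 0.984), and retinoic acid after quantile normalization (0.970) and length and GC correction (0.606; range 0.838 to 0.999). Stromal markers (0.619 to 0.883) and epithelial markers (0.818 without a filter; 0.520 to 0.937) did so too. Of the added lists, tRNA synthetases changed direction with fry (0.708) and on leaving out a library (0.637 to 1), and mTORC1 regulators with 5 TPM (0.829), quantile normalization (0.933) and on leaving out a library (0.690 to 0.981). The cause was not tested for these changes. The list of cytosolic ribosomal proteins kept its call with the 52 members of at least 100 TPM (adjusted p = 2.4e-09) at the preset correlation, and lost it at an estimated one (adjusted p = 0.142). Depth is unknown and limits low genes most.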

Other observations

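The added gene lists, the correction for length and GC content, the HIF list without DDIT4, the comparison of S phase with G2/M genes, and both tests on genes near the floor were chosen after the main results were seen. Proteasome subunit genes fell in 19 of 31 cases and rose in 0, with a median of -0.28 (camera adjusted p = 6.75e-07; adjusted p = 0.0505 with an estimated correlation). PSMD1 fell from 170.8 ± 8.0 to 98.2 ± 3.9 TPM and PSMD12 by 0.75 ± 0.08. Nuclear transport genes fell in 14 of 28 cases and rose in 0 (adjusted p = 0.000217; adjusted p = 0.320 with an estimated correlation), with RANBP1, a Ran-binding protein, at 777.2 ± 19.7 and 516.8 ± 5.3 TPM. Mitochondrial ribosomal protein genes had 18 of 45 down and 2 up (adjusted p = 0.00115; adjusted p = 0.101 with an estimated correlation), among them MRPL20, which fell by 0.50 ± 0.05.

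Of the Fanconi and homologous recombination list 13 of 22 fell and 1 rose (adjusted p = 0.000387; adjusted p = 0.101 with an estimated correlation), and EXO1 fell by 0.93 ± 0.07. Mismatch repair and checkpoint genes fell in 9 of 17 cases and rose in 0 (adjusted p = 0.000387; adjusted p = 0.101 with an estimated correlation), with CLSPN, a mediator of the replication checkpoint, at 16.9 ± 2.5 and 6.1 ± 0.4 TPM. Circadian clock genes rose in 6 of 15 cases and fell in 0, with a median of 0.51, or 0.258 with a pseudocount of 5 (adjusted p = 0.00451; adjusted p = 0.101 with an estimated correlation). The clock repressor NR1D1 rose from 6.3 ± 0.9 to 21.7 ± 2.7 TPM, and DBP from 13.5 ± 0.9 to 31.5 ± 4.2 TPM. The other 7 of the 15 added lists, on cytosolic and mitochondrial tRNA synthetases, chaperonins, microRNA processing, amino acid transporters, axon guidance and mTORC1 regulators, did not pass in the main analysis, with adjusted p from 0.0640 to 0.909. Chaperonins passed without a filter (adjusted p = 0.0155), without DMSO replicate 1 (0.0353) and with fry (0.000962), and axon guidance without a filter (0.0389) and with fry (0.000968). Fry also called microRNA processing (0.005) and amino acid transporters (0.00437). The mean log2 level of S phase genes minus that of G2/M genes was -0.36 ± 0.05 in DMSO and -1.11 ± 0.05 in NEN libraries (SD, n = 3, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). ATF4 mRNA itself did not pass the test (0.10, adjusted p = 0.138), though it did after quantile normalization (0.17).

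After NEN 25 of 56 ribosomal protein genes rose and 0 fell, while 18 of 29 genes of ribosome biogenesis and growth fell and 1 rose. With an estimated correlation camera gave adjusted p = 0.160 and 0.0972. The list of ribosome biogenesis and growth also holds growth genes outside the ribosome, so its counts are not of ribosome biogenesis alone. The ribosomal protein median was 0.21 once the trend with transcript length and GC content was removed. That argues against this trend as the whole cause. Median-ratio scaling moves all genes of a library alike. Its ribosomal median of 0.23 thus followed from the median of -0.025 over all genes and tests little. A factor common to all genes would have raised the median over all genes as well, and that was -0.025. This argues against such a factor as the cause of the higher ribosomal median. Quantile normalization lowered the ribosomal median to 0.118 (camera adjusted p = 0.00889). It forces the whole distribution of each library to be alike, which can also shrink a true shift of abundant genes. The lower value therefore does not show that scaling took part, and a distortion that depends on expression level stays open. A candidate explanation is a shared change of mRNAs with a 5' terminal oligopyrimidine tract, whose translation and stability depend on mTORC1. The translation factors and other non-ribosomal mRNAs of that class had a median of 0.20, with 15 of 25 up and 0 down. EEF2 was among those that rose (0.61 ± 0.05). For this class camera gave p = 3.68e-07, with an adjusted p = 2.76e-06, or 0.101 with an estimated correlation. RNA selection and mRNA stability stay open and this remains a hypothesis. Histone genes, listed as a possible sign of RNA selection, were also higher (median 0.73, camera adjusted p = 0.0155, or 0.376 with an estimated correlation). They were not past the threshold with 5 TPM (adjusted p = 0.127) or without a filter (median 0.152, adjusted p = 0.221). A change of histone mRNA in the cells themselves would give the same rise and was not told apart from RNA selection.

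HIF targets were higher by camera's preset correlation while HIF1A mRNA was lower (adjusted p = 0.229 for the list with an estimated correlation). Without DDIT4, which ATF4 also regulates, the limma camera test gave an adjusted p = 0.0146 (0.00292 before adjustment), and 0.376 with an estimated correlation. A second list of HIF targets had a median of 0.20 (0.122 with a pseudocount of 5) with 5 of 18 up and 1 down. Its camera p was 0.0088, with an adjusted p = 0.0165, or 0.101 with an estimated correlation. ANKZF1 rose by 0.83 ± 0.10 and WSB1 fell by 0.74 ± 0.16. The first list was mixed: 10 of 22 members rose, 1 fell and 11 did not pass. Among those that did not pass were EGLN3 (-0.215), EGLN1 (-0.075) and ANKRD37 (0.033). The rises fit activation of the HIF pathway as a hypothesis, which may act through HIF protein that mRNA does not show. The members that did not rise limit it. The call of that second list was lost with a minimum of 5 TPM (adjusted p = 0.0738), and other regulators of the same genes stay open.

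Some genes that most cells express at high levels were listed near the floor in both groups. ACTB, cytoplasmic actin, had group means of 32.8 and 26.1 TPM, LDHA 6.75 and 6.79 TPM, RPS7 26.5 and 16.3 TPM and RPL26 31.3 and 19.7 TPM. COX6B1 was listed at 0 in DMSO replicate 1 and at 0.23, 2.43, 0.214, 2.79 and 4.21 TPM in the other libraries. Reads assigned to listed pseudogenes do not account for this, since those of 6 such genes summed to at most 6.86 TPM in any library. At least 66500 TPM per library lay outside the listed names, which could include transcripts of these genes, but unlisted noncoding RNA would leave the same gap and the 2 cannot be told apart.

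With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3773 genes, and the highest of the others gave 1. Every other split mixes both treatments in each group, so low counts there follow from the treatment difference itself. Only 1 of the 10 splits, the real one, gave as many, and this decides nothing.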
